A study of Homo sapiens with 12 samples.

How the data were processed

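RNA came from ES-2 cells carrying a control vector or an SRMS shRNA, and per the labels' protocols poly(A) RNA was selected with oligo(dT) beads, stranded TruSeq libraries were prepared and paired ends were read on a NovaSeq instrument. Per the submitters' processing notes the tools were FastQC, cutadapt, HISAT2, StringTie and edgeR, with genome build GRCh38; their versions, settings and filter on low genes are not given in the sources used here. The labels give 12 samples in 4 groups of 3, which cross the construct with PBS or 15 µM cisplatin for 8 hours. The deposited table used here has 6 columns, 3 for the vector and 3 for SRMS shRNA, all with cisplatin. The PBS samples are not analysed here, so the knockdown comparison in PBS, both cisplatin effects and their difference, which had been planned, were not run.

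The deposited table names its values log CPM, but they are a linear signal: the authors' deposited values are whole reads divided by an effective library size and scaled as for CPM, and columns sum to between 973481 and 1047470. Dividing each column by the worth of 1 read gave whole numbers, within a tolerance of 0.1, for at least 99.99% of values in every library. The recovered totals of 28009232 to 56855428 reads are those of the listed genes. The plan had assumed log2 CPM, so the main test was limma with a mean-variance trend on log2(value + 0.5), and fold changes on that scale understate the change of low genes. Before the data were examined, the groups, the main design without a replicate block, the gene lists, the rule for named genes and the main alternatives were fixed. The pseudocount was chosen before any test was run.

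The table has 14042 rows, all of which matched Ensembl identifiers of GENCODE release 29 on GRCh38, and 14007 had a symbol in the gene name table. By that annotation 14036 are protein coding and 6 are polymorphic pseudogenes. The 13 rows for the Y copy of pseudoautosomal genes were left out, which left 14029 genes. Coordinates, transcript lengths and sequences come from that annotation, with 1 transcript per gene, taken as coding, principal by APPRIS where marked, and longest.

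Tests used limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all 14029 genes and a threshold of 0.05. Since only these groups had values, the fit held the 6 libraries alone, and a fit of only the groups compared, which had been intended as a second setting, was the same fit. Gene lists were tested with camera (preset correlation 0.01) if at least 5 members were measured, which held for 31 of 34 lists, with adjustment over the 31. Camera with an estimated correlation and fry were run beside it. The lists cover p53, AP-1, MAPK feedback, JNK, the SRC family, BCL2, death receptors, histones, repair, cell cycle, stress responses, NRF2, metallothioneins, NF-κB, interferon, cholesterol, hypoxia, respiration, ribosomal proteins, snoRNA hosts, matrix, epithelium, YAP/TEAD, TGFβ, platinum transport, autophagy and markers of leukocytes, endothelium and fibroblasts. SRMS was always named. Also named were the 8 genes with the highest and the 8 with the lowest log2 fold change among genes past the threshold, with no overlap between groups, a mean of at least 2 on the log2 scale in the higher group and a symbol, and up to 4 members with the smallest adjusted p in each list described; the text gives only part of the genes that this rule picks, and 1 of them is not reported here.

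Replicates were compared before they were averaged. The chi-square per gene between replicates 2 and 3, over genes with 200 to 5000 reads in the pair, was 1.78 for the vector and 1.63 for SRMS shRNA, against 3.37 to 4.63 for pairs with replicate 1. For genes of 5000 reads or more it was 2.49 and 2.79, against 26.7 to 53.1. For genes with 20 to 200 reads it was 1.80 and 1.64, against 1.68 to 1.79, so replicate 1 did not stand apart there. Replicates 2 and 3 still differed in abundant genes, so all 3 were kept, and an alternative averages replicates 2 and 3. The labels number replicates 1 to 3 in each group without saying what a number shares. Deviations from the group means correlated between same-numbered libraries with r of 0.486, 0.238 and 0.225 across genes, all above 0.1, so the numbers were taken to pair the samples. Replicate 2 of 1 group and replicate 3 of the other also correlated, with r of 0.198 and 0.202. These correlations set replicate 1 apart but do not show that replicates 2 and 3 pair by number. Fits with the replicate block assume that they do.

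Settings fixed in advance for comparison were median and quantile scaling, a minimum mean of 1 on the log2 scale, a pseudocount of 1, no trend, array weights, the replicate block, each library left out and an absolute log2 fold change of at least 1. Added after seeing the data were a pseudocount of 0.1, count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0), the averaged replicates, replicate 1 of both groups left out, genes with CGTGTC left out, the block with a loess trend on transcript length and GC content removed, and, for SRMS, the block with each pair left out. edgeR called 7924 of 13164 genes that passed its filter, and 8058 with no filter. On simulated counts for the comparison of SRMS shRNA with vector in cisplatin, with 14029 genes and 200 changed, the main test recovered 61.4% of genes changed by 0.5 on the log2 scale, 99.7% at 1 and 100% at 2, and 3.14% of its calls were false. The simulated counts had a dispersion of 0.01 and far fewer changed genes than were called in the data. These shares therefore need not hold for the real calls. Hexamers were counted in 3′ UTRs of at least 50 nt with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A shift of -0.15 planted on a random hexamer was found in 20 of 20 simulated draws over 11063 genes.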

Results

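Poly(A) RNA was sequenced from ES-2, a human ovarian cancer cell line, carrying either a control vector or a short hairpin RNA (shRNA) directed against SRMS. SRMS is a non-receptor tyrosine kinase of the BRK family. Cisplatin, a platinum drug that crosslinks DNA, was given at 15 µM for 8 hours, and phosphate-buffered saline (PBS) served as the control treatment. The series holds 12 samples, and values were used for 6 of them, 3 with the vector and 3 labelled SRMS shRNA, all given cisplatin. The 6 PBS samples are not analysed here, so every comparison below is between the constructs within cisplatin, and no response to cisplatin itself was measured. Reads recovered from the deposited values came to 29072793, 45323697 and 56855428 in vector replicates 1, 2 and 3, and to 28009232, 38072051 and 32577706 in the replicates labelled SRMS shRNA. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

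SRMS, the gene that the hairpin was meant to lower, was not lower in the libraries labelled SRMS shRNA. Its deposited signal, which is reads scaled by the effective library size as for CPM, was 0.397 ± 0.384 with the vector and 0.755 ± 0.384 in the libraries labelled SRMS shRNA (mean ± SD, n = 3 each). The gene (ENSG00000125508) lies on the minus strand of chromosome 20, from 63540810 to 63547504 in GRCh38. It was counted in few reads, with 2, 14 and 47 in the vector replicates and 9, 39 and 27 in the replicates labelled SRMS shRNA. The log2 fold change was 0.52 (SE 0.303, 95% interval -0.15 to 1.19), with a limma adjusted p of 0.168. A two-sided exact permutation test of the 3 against 3 values gave p = 0.2, where the smallest p possible is 0.1. With the replicate number as a block the same log2 fold change of 0.52 had a limma adjusted p of 0.00782, toward more SRMS rather than less, and the value was higher in 3 of 3 same-numbered pairs. Without pair 2 it was 0.30 under the block (limma adjusted p = 0.17). Leaving out vector replicate 3 gave a log2 fold change of 0.84 (limma adjusted p = 0.0281), and leaving out SRMS shRNA replicate 1 gave 0.79 (limma adjusted p = 0.0245). Leaving out vector replicate 1 gave 0.23 (limma adjusted p = 0.527) and leaving out SRMS shRNA replicate 2 gave 0.33 (limma adjusted p = 0.442). With the block and the trend with transcript length and GC content removed it was 0.28 (limma adjusted p = 0.144). Since no fall of the target was seen, directions below are given for the libraries labelled SRMS shRNA, as their labels name them.

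**Figure D1:**
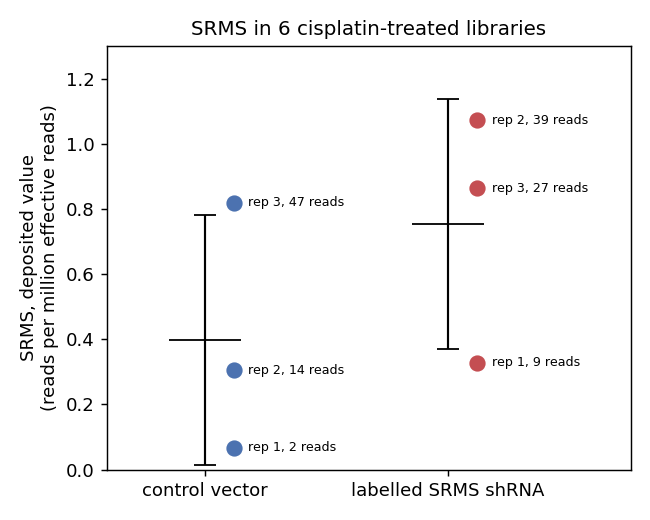
SRMS in the 6 libraries given cisplatin, as the deposited signal scaled as for CPM (vertical axis), for the control vector and for the libraries labelled SRMS shRNA. Points are libraries with their replicate number and reads, the horizontal bar is the mean and the error bar is the SD; the means were 0.397 and 0.755, and the ranges of the groups overlap.

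The question posed by the series is how gene expression under cisplatin differs when SRMS is targeted. GALNT2, a glycosyltransferase that starts O-linked glycosylation, had the largest drop on the scale of log2(value + 0.5). It fell from 138 ± 0.768 with the vector to 10.4 ± 0.369 in the libraries labelled SRMS shRNA (mean ± SD, n = 3 each). ACTN4, an actin-crosslinking alpha-actinin, fell from 755 ± 9.71 to 236 ± 4.38, and GLUL, glutamine synthetase, fell from 6.41 ± 0.42 to 0.781 ± 0.358. GYPC, a membrane glycoprotein known from red cells, rose from 1.92 ± 0.264 to 7.75 ± 1.03, and APOE, a lipid carrier, rose from 5.86 ± 0.531 to 18.6 ± 2.14. The constructs differed in 7969 of 14029 genes by limma at an adjusted p under 0.05, with 3736 higher and 4233 lower in the libraries labelled SRMS shRNA.

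Most of these differences were small, with a median absolute log2 fold change of 0.38, and 5575 of the 7969 were under 0.5. Only 292 reached an absolute log2 fold change of 1, of which 105 were higher and 187 lower. The values of the groups did not overlap in 62.7% of the genes tested. Chance gives 10% if the 6 libraries are exchangeable, which the closeness of replicates 2 and 3 puts in doubt. Among genes with 200 reads or more, replicates 2 and 3 of each group lay far closer to each other than either did to replicate 1, and with those 2 averaged as a single sample limma called 6068 genes, 2781 higher and 3287 lower. Aligning the libraries on their median moved the median of all genes by 0.16 on the log2 scale and changed the split to 6254 higher and 2510 lower, so the balance of higher against lower genes depends on the scaling.

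The 8 genes with the largest increases, by the rule fixed in advance, had log2 fold changes from 1.45 to 1.77. After GYPC (ENSG00000136732, chromosome 2, 126655933 to 126696670, plus strand) came PYGM, the muscle glycogen phosphorylase, at 1.71 (SE 0.0845, limma adjusted p = 3.09e-07), which rose from 3.88 ± 0.236 to 13.8 ± 0.814. S100A14, a calcium-binding protein, had 1.59, as did APOE, and MAP3K7CL had 1.56. MMP10, a matrix metalloproteinase, rose from 2.89 ± 0.446 to 9.24 ± 0.6. The list ended with CPNE7, a calcium-dependent phospholipid-binding protein, at 1.49, and NNMT, nicotinamide N-methyltransferase, at 1.45.

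The 8 genes with the largest decreases had log2 fold changes from -3.67 to -1.68. GALNT2 (ENSG00000143641, chromosome 1, 230057990 to 230282124, plus strand) stood lowest at -3.67 (SE 0.0455, limma adjusted p = 1.5e-11). TRIM58, at -2.73, fell from 4.94 ± 0.239 to 0.327 ± 0.159, which as a ratio of means is a larger drop than that of GALNT2. GLUL had -2.47. SPATS2L, at -2.28, fell from 146 ± 7.74 to 29.7 ± 1.62. MBOAT2, a membrane-bound acyltransferase, had -1.94, the transcription factor NFATC4 had -1.79 and TRAFD1 had -1.70. ACTN4 (ENSG00000130402, chromosome 19, 38647649 to 38731583, plus strand) had -1.68 (SE 0.0312, limma adjusted p = 4.8e-10). The hexamer CGTGTC, which a scan of these same fold changes picked out, lies in the 3′ UTR or coding sequence of 6 of these 8 genes. It lies in 1 of the 8 with the largest increases, against 25.5% of all genes tested. These counts are therefore no independent support, and the share over all genes is not matched for transcript length.

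**Figure D2:**
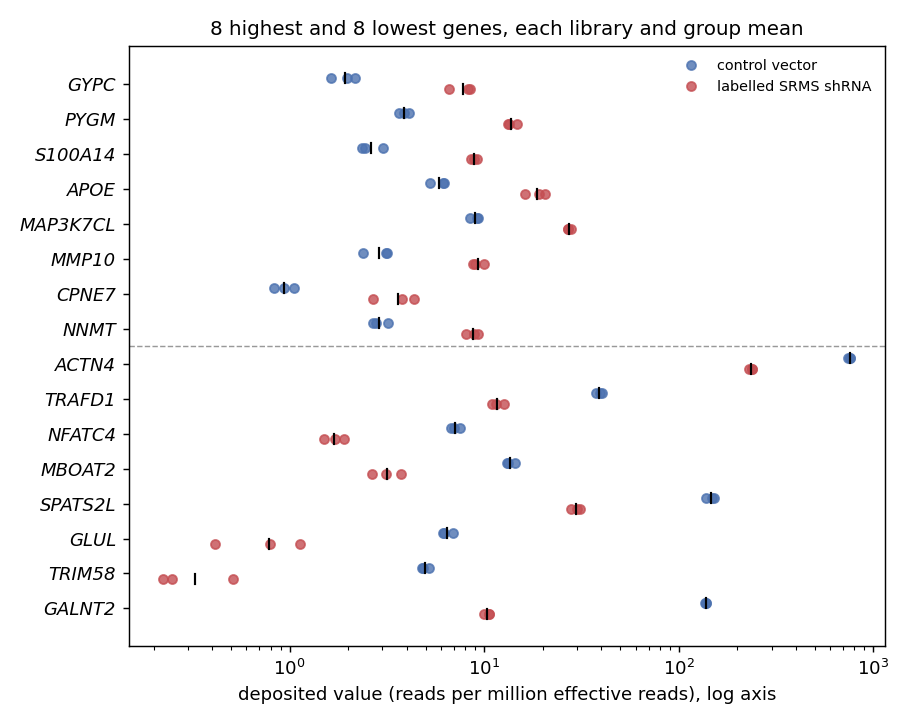
Deposited signal scaled as for CPM (horizontal log axis) of the 8 genes with the largest increases, above the dashed line, and the 8 with the largest decreases, below it. Points are the 3 libraries of each group and the vertical ticks are group means; GALNT2 drops from 138 to 10.4 and GYPC rises from 1.92 to 7.75, with no overlap between the groups.

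Genes for protein synthesis and respiration were higher as groups in the libraries labelled SRMS shRNA. Of 40 ribosomal protein genes, 38 rose and 0 fell, by limma (39 and 0 adjusted over the list alone), with a median log2 fold change of 0.28. RPLP1, a protein of the large subunit, rose from 2145 ± 38 to 2941 ± 90.6, and RPS19, of the small subunit, from 668 ± 8.34 to 921 ± 36.5. Of 25 nuclear genes for oxidative phosphorylation, 24 rose and 0 fell (24 and 1 adjusted over the list alone), with a median of 0.38, among them UQCRH of complex III and COX4I1 of cytochrome c oxidase, from 431 ± 8.21 to 573 ± 28.7. Of 13 mitochondrially encoded mRNAs, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with MT-ND1 going from 3377 ± 221 to 4960 ± 267. Camera, which sets a list against all other genes, gave adjusted p of 2.29e-11 for the ribosomal proteins, 7.11e-08 for the nuclear respiratory genes and 0.00016 for the mitochondrial mRNAs. With an estimated correlation between genes the adjusted p were 0.325, 0.325 and 0.412. The list medians, 0.28, 0.38 and 0.42, were 0.44, 0.54 and 0.58 with the libraries aligned on their median. With quantile scaling they were 0.12, 0.32 and 0.24.

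Shares of reads and transcript length differed between the constructs as well. Mitochondrial mRNAs made up 4.15% to 4.83% of reads in the vector libraries and 5.40% to 6.12% in those labelled SRMS shRNA. Genes also differed by transcript length. Among the 2806 genes with the shortest transcripts (median 1259 nt) 1480 were higher and 187 lower, and among the 2806 with the longest (median 7074.5 nt) 269 were higher and 1527 lower. The median log2 fold changes of these groups were 0.23 and -0.23, and 0.39 and -0.07 with the libraries aligned on their median. With the replicate block and the trend with length and GC content removed, 24 ribosomal protein genes were higher and 6 lower, with a median log2 fold change of 0.056. The nuclear respiratory genes then had 18 higher and 2 lower, with a median of 0.16 against 0.38, and the mitochondrial mRNAs 10 higher and 2 lower, with a median of 0.17 against 0.42.

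Histone genes were higher as well. Of 16 measured, 12 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.44 and a camera adjusted p of 7.04e-05 (adjusted p = 0.305 with an estimated correlation). H2BC5 rose from 3.29 ± 0.324 to 7.78 ± 0.35, and the linker histone H1-2 from 6.32 ± 0.225 to 13.4 ± 0.986. Many histone genes are near-identical copies and many of their mRNAs lack a poly(A) tail, so single members are uncertain in these libraries. With length and GC trend removed under the block, 10 were higher and 0 lower, with a median of 0.28. The median was 0.60 with the libraries aligned on their median and 0.29 with quantile scaling.

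Immediate early genes of the AP-1 group were mostly higher. Of 26 measured, 15 rose and 5 fell (15 and 5 adjusted over the list alone). FOS rose from 29.3 ± 1.51 to 59.8 ± 3.35, FOSB from 13.8 ± 0.958 to 29.8 ± 0.279 and ATF3, a stress-induced transcription factor, from 24.0 ± 1.63 to 51.1 ± 4.59, whereas FOSL2 fell from 63.0 ± 2.11 to 38.4 ± 1.71. The camera adjusted p was 0.0352 (adjusted p = 0.451 with an estimated correlation). It lay above 0.05 without vector replicate 1 (0.0603), SRMS shRNA replicate 2 (0.0505) or SRMS shRNA replicate 3 (0.0601), with median and quantile scaling (0.0548 and 0.0571), among genes with a mean of at least 1 (0.0503), without genes holding CGTGTC (0.126) and with the length and GC trend removed (0.218), in a range from 0.0127 to 0.218. The median of the list was 0.32. Without vector replicate 1, SRMS shRNA replicate 2 or SRMS shRNA replicate 3 it was 0.27, 0.30 or 0.28. Among genes with a mean of at least 1 it was 0.28. It was 0.48 with median scaling, 0.30 with quantile scaling, 0.25 without genes holding CGTGTC and 0.31 with the length and GC trend removed. The counts were 15 higher and 8 lower with the block, and 14 higher and 10 lower with that trend removed as well.

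Lists past the camera test toward lower values were those of G1/S genes, YAP/TEAD targets and NRF2 targets. Of 25 genes of the G1/S transition, 1 rose and 15 fell (1 and 15 adjusted over the list alone), with CCNE2, a cyclin, going from 122 ± 1.76 to 85.9 ± 1.54 and UHRF1 from 124 ± 5.62 to 78.5 ± 7.76. Of 15 YAP/TEAD targets, 2 rose and 9 fell (2 and 9 adjusted over the list alone), led by ANKRD1, from 159 ± 1.02 to 74.7 ± 0.799, and including AJUBA and CCN1. Of 20 NRF2 targets, 0 rose and 10 fell (0 and 10 adjusted over the list alone). They included GCLM and GCLC, the subunits of the enzyme that starts glutathione synthesis, at -0.66 and -0.57, TXNRD1, a thioredoxin reductase, at -0.78, and SLC7A11, the cystine transporter, from 17.7 ± 1.37 to 7.77 ± 0.886. Camera adjusted p were 0.0055, 0.00984 and 0.0148 (adjusted p = 0.305, 0.305 and 0.325 with an estimated correlation).

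With the libraries aligned on their median, the G1/S list had 6 higher and 9 lower (camera adjusted p = 0.0533), the YAP/TEAD list 2 and 8, and the NRF2 list 4 and 8. The median of the G1/S list was then -0.07 against -0.23, and that of the YAP/TEAD list -0.25 against -0.41. The median of the NRF2 list changed sign, from -0.11 to 0.05, though its camera direction stayed down (adjusted p = 0.0376). That median was -0.21 with quantile scaling, -0.27 among genes with a mean of at least 1 and -0.22 without replicate 1 of both groups. Leaving out single libraries gave -0.18 to -0.10. With the transcript length and GC trend removed under the block, 1 G1/S gene was higher and 17 lower (17 lower with the block alone), 3 YAP/TEAD targets higher and 10 lower (11 with the block alone), and 0 NRF2 targets higher and 16 lower (11 with the block alone). The list medians then were -0.14 for G1/S, -0.22 for YAP/TEAD and -0.21 for NRF2, against -0.23, -0.41 and -0.11.

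**Figure D3:**
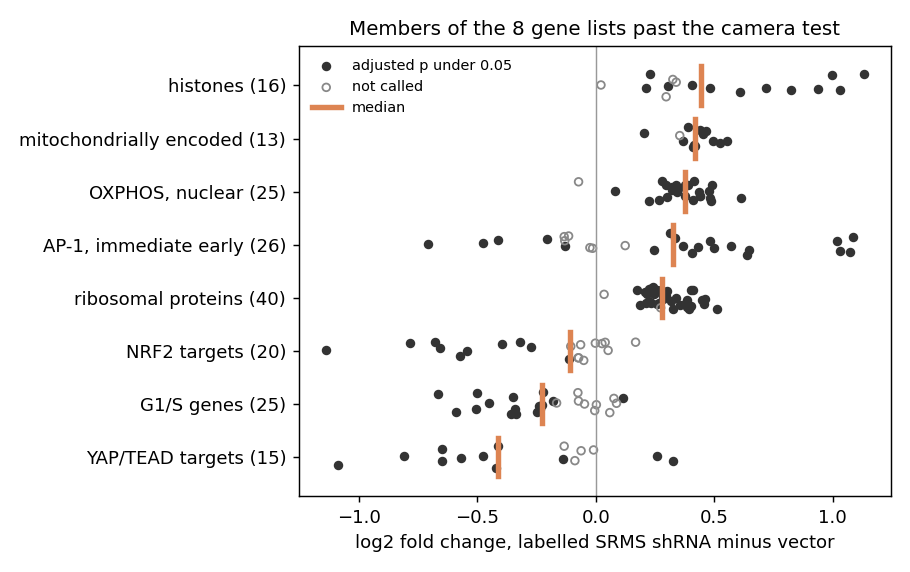
Log2 fold change (value plus 0.5) of each member of the 8 gene lists past the camera test, libraries labelled SRMS shRNA minus vector (horizontal axis), with the number of members measured in parentheses. Filled points passed limma's adjusted p of 0.05, open points did not, and the thick bar is the list's median, from -0.41 for YAP/TEAD targets to 0.44 for histones; with the libraries aligned on their median the NRF2 median turns to 0.05, and the medians of G1/S and YAP/TEAD are -0.07 and -0.25.

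Lists tied to cell death and kinase signalling did not pass the camera test, though members moved in both directions. Of 18 BCL2 family genes, 6 rose and 5 fell (7 and 5 adjusted over the list alone). PMAIP1, which encodes the pro-apoptotic NOXA, rose from 95.3 ± 4.41 to 157 ± 6.76, and the anti-apoptotic MCL1 fell from 145 ± 3.61 to 94.0 ± 3.56. Of 21 genes for death receptors and caspases, 1 rose and 11 fell (1 and 12 adjusted over the list alone; camera adjusted p = 0.112), including FADD, from 134 ± 2.17 to 89.2 ± 0.905, and TNFRSF1A, from 111 ± 0.71 to 66.1 ± 3.43. Of 26 p53 targets, 5 rose and 11 fell (5 and 11 adjusted over the list alone), with GADD45A at 0.69 and MDM2 at -0.67. Among 18 components of the JNK cascade, 1 rose and 7 fell (1 and 7 adjusted over the list alone), MAP3K1 among them at -0.69. Of 19 MAPK feedback genes, 6 rose and 9 fell (6 and 9 adjusted over the list alone), with SPRED2 at -0.94. In the list of the SRC and BRK families, which also holds CSK and DOK1, 3 of 10 rose and 2 fell (3 and 2 adjusted over the list alone). SRC itself fell from 25.2 ± 0.338 to 12.8 ± 0.324. The camera adjusted p of these lists, the death receptors aside, ran from 0.21 to 0.882. With the libraries aligned on their median the balance of the p53, MAPK feedback and death receptor lists turned to 7 higher and 6 lower each, and that of the JNK list to 6 and 5. For the BCL2 family the median, 0.12, and camera pointed up while fry pointed down. With the length and GC trend removed under the block, the BCL2 family turned to 5 higher and 7 lower (median -0.12, camera down), the JNK list to 8 and 8 (median 0.01, from -0.12) and the SRC family list to 4 and 2 (median 0.10, from -0.05).

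DNA repair genes were also mixed. Of 20 recombination and checkpoint genes, 3 rose and 11 fell (4 and 12 adjusted over the list alone), with BARD1 going from 12.3 ± 0.615 to 5.23 ± 0.0901 and XRCC2 from 14.5 ± 1.55 to 7.49 ± 0.275. The camera adjusted p was 0.0766, and it was 0.0371 with the replicate block, 0.0329 without replicate 1 of both groups and 0.0472 without SRMS shRNA replicate 1, in a range from 0.0329 to 0.308 at the preset correlation (adjusted p = 0.391 with an estimated correlation). With the block 4 were higher and 12 lower, and with the length and GC trend removed as well 4 and 7, where the median changed sign from -0.20 to 0.02. Of 25 excision and crosslink repair genes, 4 rose and 11 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.139), with DDB2 at 0.40 and FANCM at -0.61. With the libraries aligned on their median these lists had 6 higher and 6 lower, and 7 higher and 6 lower. Of 17 genes for platinum transport and thiols, 3 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.139). LRRC8A, a subunit of the volume-regulated anion channel, fell from 61.9 ± 2.93 to 21.3 ± 2.04. Of 4 metallothioneins, too few for camera, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with MT2A going from 1129 ± 64.7 to 1670 ± 142; these genes share much of their sequence.

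Inflammatory and stress lists stayed above the camera threshold too. Of 20 NF-κB and cytokine genes, 2 rose and 10 fell, with NFKB1 going from 31.9 ± 1.2 to 14.7 ± 0.761 and the chemokine CXCL8 from 118 ± 5.28 to 81.7 ± 0.665. Of 21 interferon response genes, 7 rose and 1 fell, with ISG15 at 0.69 and the RNA sensor RIGI at -0.77. The ATF4 list had 10 higher and 6 lower of 21, the endoplasmic reticulum chaperones 9 and 3 of 17, the heat shock genes 2 and 7 of 16, and the hypoxia and glycolysis genes 9 and 7 of 20. Cholesterol synthesis had 4 higher and 7 lower of 21, autophagy and lysosome genes 9 and 3 of 20, and G2/M genes 7 and 10 of 22, with CCNF going from 42.4 ± 0.782 to 19.0 ± 0.437. TGFβ/SMAD targets had 3 higher and 5 lower of 12, where ID2 rose from 11.1 ± 1.57 to 29.1 ± 3.92 and ID3 fell from 71.4 ± 3.75 to 32.0 ± 3.56. Adjusted over the list alone, the counts of all lists in this paragraph were the same. With the libraries aligned on their median the balance turned for NF-κB genes (6 higher and 5 lower), heat shock (7 and 4), cholesterol synthesis (12 and 2), G2/M (11 and 7) and TGFβ/SMAD (4 and 3). Camera adjusted p ran from 0.139 to 0.833. That of the heat shock list was 0.000894 with quantile scaling and that of the NF-κB list 0.0429 with the length and GC trend removed (adjusted p = 0.451 and 0.325 with an estimated correlation, without those changes).

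Lists of markers of cell state and of other cell types did not pass the camera test against other genes. Fry, which tests a list against no change, gave adjusted p of 0.00209 toward higher leukocyte markers, 0.00237 toward higher epithelial genes and 0.00139 toward lower fibroblast markers. It passed 29 of the 31 lists tested, so these values do not set the marker lists apart. Of 24 mesenchymal and matrix genes, 8 rose and 8 fell (13 and 5 with the libraries aligned on their median, 10 and 7 with the length and GC trend removed under the block), with COL1A1 going from 1238 ± 1.77 to 816 ± 3.24 and LOX, a collagen-crosslinking enzyme, from 371 ± 25.7 to 605 ± 39.4. Of 11 epithelial and ovarian genes, 7 rose and 1 fell, which was KRT7 at -0.36. Of 8 leukocyte markers, 5 rose and 1 fell (camera adjusted p = 0.0886), most at low values, with CD14 going from 0.879 ± 0.197 to 3.24 ± 0.37. Of 7 fibroblast markers, 2 rose and 2 fell (2 and 3 adjusted over the list alone), and the counts of the other lists in this paragraph were the same adjusted over the list alone. Only 3 endothelial markers were measured, too few for camera, and CDH5 fell from 15.2 ± 1.09 to 6.12 ± 0.763. None of the snoRNA host genes was measured (0 genes), since the table holds protein-coding genes, apart from 6 polymorphic pseudogenes.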

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

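The pseudocount of 0.1, the count tests, the averaged replicates, replicate 1 left out of both groups, genes with CGTGTC left out, the block with length trend removed and the block with each pair left out were chosen after seeing the data. Over all alternatives without an effect size threshold, the count of genes lay between 5816 and 9154 against 7969, and 6068 with replicates 2 and 3 averaged. The replicate block, which takes same-numbered samples as pairs, gave 9154 genes. Aligning the libraries on their median gave 6254 higher and 2510 lower. An absolute log2 fold change of at least 1 left 292 genes, 105 higher and 187 lower, and leaving out genes with CGTGTC left 2818 lower of 10447 genes tested, since by construction it removes genes that were lower more often. Leaving out each library gave 6895 to 8324 genes. The comparisons with PBS were not run, and a fit of only the groups compared was the fit reported.

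For SRMS, the log2 fold change stayed above 0 in every setting that gave a value, from 0.23 to 0.99, and its size depended on the setting, with 0.99 for a pseudocount of 0.1, 0.34 for a pseudocount of 1, 0.79 by edgeR and 0.92 by DESeq2; the minimum mean of 1 and leaving out genes with CGTGTC both removed SRMS. It passed the threshold, toward higher SRMS, with the replicate block (0.52, adjusted p 0.00782) and without replicate 1 of both groups (0.51, adjusted p 0.0331), but not with the block and the length and GC trend removed (0.28, adjusted p 0.144) or with replicates 2 and 3 averaged (adjusted p 0.225). Leaving out single libraries gave 0.23 to 0.84, past the threshold without vector replicate 3 or SRMS shRNA replicate 1; the cause was not tested. Under the block, leaving out pairs 1, 2 and 3 gave 0.51, 0.30 and 0.76, with adjusted p of 0.015, 0.17 and 0.000396. The adjusted p ranged from 0.000396 to 0.527. Its 2 to 47 reads limit what can be seen.

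Of 31 lists, 8 passed with the preset correlation, 0 with an estimated correlation and 29 by fry, which does not compare a list with other genes. The block added the recombination list (adjusted p 0.0371) and, SRMS aside, changed no other call among the 31 lists and the 138 named genes past the threshold. Over 21 settings 5 of those genes lost the call in 8 cases, with median or quantile scaling or with the length and GC trend removed; the cause was not tested.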

Other observations

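The gene families and genes named with them in the next paragraph, the hexamer scan, and the tests of base composition, of the site in SRMS, of read number and of swapped labels, were chosen only after the result was seen. Adjusted p of those families do not account for that choice.

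Genes for chromatin regulators were lower as a family in the libraries labelled SRMS shRNA, with 35 of 45 lower and 2 higher by limma and a median log2 fold change of -0.65. SIN3A, a corepressor scaffold, fell from 37.1 ± 1.97 to 11.4 ± 0.751, the acetyltransferase gene EP300 from 62.4 ± 0.413 to 31.5 ± 0.225, and SETD2, a histone methyltransferase, from 50.7 ± 1.2 to 24.3 ± 1.01 (mean ± SD, n = 3 each). With the libraries aligned on their median, 31 were lower and 4 higher. Of 421 ZNF genes, 177 were lower and 49 higher, which turned to 110 and 102 with the median alignment. Genes for MHC class I presentation were mostly higher, 9 of 14 against 2 lower, with HLA-B going from 18.1 ± 0.932 to 41.2 ± 2.13 and B2M from 489 ± 6.35 to 668 ± 20.2; HLA genes share sequence, so single members are uncertain. Mitochondrial ribosomal proteins were higher in 51 of 76 genes and lower in 3, and proteasome subunits higher in 22 of 37 and lower in 4. Camera, adjusted over these 5 families, gave 2.75e-11 for the chromatin regulators, 0.000792 for the ZNF genes, 0.00221 for MHC class I, 2.8e-09 for the mitochondrial ribosomal proteins and 0.000454 for the proteasome, and with an estimated correlation the adjusted p were 0.126, 0.278, 0.0833, 0.223 and 0.0833. With the length and GC trend removed under the block, 7 chromatin regulators were higher and 30 lower (median -0.44), 76 ZNF genes higher and 170 lower (-0.09, against -0.19), 6 MHC class I genes higher and 1 lower (0.14, against 0.28), 34 mitochondrial ribosomal proteins higher and 17 lower (0.05, against 0.23), and 17 proteasome subunits higher and 9 lower (0.05, against 0.13). The camera adjusted p were then 2.43e-07, 0.0459, 0.0379, 0.0459 and, for the proteasome, 0.149. CGTGTC lies in the 3′ UTR or coding sequence of 22 of the 45 chromatin regulators, or 48.9%. The share over all genes tested was 25.5%, which is not matched for transcript length. The genes with CGTGTC include SIN3A but not EP300 or SETD2. Of the 23 without it 17 were lower and 1 higher (median -0.57, camera adjusted p 4.2e-08, and 0.279 with an estimated correlation). Without genes holding CGTGTC the camera adjusted p was 0.135 for MHC class I, and the other 3 families stayed past the threshold at the preset correlation. The 9 MHC class I genes left had a median of 0.26, with 5 higher and 2 lower, against 0.28 for all 14.

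Transcript length followed the group: across 14029 genes, which are not independent replicates, Spearman's rho of transcript length with the log2 fold change was -0.456, and -0.468 among 10035 genes with no CGTGTC in their transcript. As to sequencing depth, rho was -0.452 with all libraries thinned to the same number of reads. Thinning keeps each gene's expected value, so it addresses only the sampling noise of unequal depth. It cannot decide on a length bias tied to depth at an earlier step. The steepest slope between libraries of 1 group was 35.1% of the slope between groups. This argues against a bias that varies from library to library whatever the group, as the whole cause, only within the spread of these replicates. Between replicates 2 and 3 the slope was -0.001 with the vector and 0.006 in the libraries labelled SRMS shRNA. The spread thus rests mostly on replicate 1 and cannot bound how far library preparations vary. A bias on transcript length alone, such as loss of long RNA, cannot be told apart from an effect of the construct. With transcript length, GC content and mean level held, genomic span kept a partial rho of -0.088 (95% interval over genes -0.103 to -0.071). This lay between the bounds set beforehand. With genomic span, GC content and mean level held, transcript length kept a larger partial rho of -0.328. An effect of the hairpin on long genes also stays open, untested.

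A scan of 4096 hexamers in the 3′ UTRs of 11063 genes, with UTR and transcript length, genomic span, GC content and mean level removed, put CGTGTC lowest, with 1116 genes, a mean shift of -0.083 on the log2 scale and a z of -8.91 against -4.73 for the next (permutation p = 0.001 over the scan, the smallest that 1000 permutations can give). Base composition is argued against, since the 89 other hexamers with the same bases had a mean shift of 0.0014 (SD 0.0128). A candidate explanation is repression by a hairpin guide whose seed pairs with CGTGTC. The SRMS transcript of 1516 nt holds the hexamer 1 time, from base 1242, as a hairpin against SRMS needs. Of 1987 transcripts of like length, 18.3% hold it. In SRMS it lies within TCGTGTC, which 3.98% of those transcripts hold. That longer stretch was read off SRMS itself, so its share does not measure how rare the match is. Genes with 2 or more sites had a lower median residual than genes with 1 site (difference -0.053, two-sided permutation p = 0.109), so the number of sites does not settle the hairpin explanation. A hairpin against SRMS should also lower SRMS, and no such fall was seen (log2 fold change 0.52, in few reads). The explanation does not account for that and stays open. The hairpin's sequence is not given in the sources used here. GALNT2, ACTN4, MBOAT2 and NFATC4 hold the site in the 3′ UTR, and on this hypothesis some of their fall may need no part played by SRMS. The median residual was -0.061 for genes with 1 site and -0.114 with 2 or more, far smaller than the falls of these genes. A typical site shift does not account for such falls, and these genes were picked as extremes of the same data.

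SRMS itself was not lower in the libraries labelled SRMS shRNA. A drop to 50% of the vector level is -0.31 on the scale of the fold change with all vector libraries. It is -0.42, -0.31 and -0.20 without vector replicate 1, 2 and 3. Too few reads to see such a drop is argued against only if same-numbered samples are pairs. The correlations between libraries do not show this for replicates 2 and 3. The 95% interval of the log2 fold change started at -0.15 with no block and at 0.18 with the block. Under the block it started at 0.14, -0.07 and 0.37 with pairs 1, 2 and 3 left out. With no block it reached past a drop to 50% without vector replicate 2 (-0.32), SRMS shRNA replicate 2 (-0.43) or SRMS shRNA replicate 3 (-0.37), so without the pairing single libraries decide it, and smaller drops are not covered. Without vector replicate 1 the interval started at -0.41, barely short of the -0.42 that applies there. Swapped group labels cannot be told apart from true ones by SRMS alone: genes with CGTGTC in the 3′ UTR were lower in the libraries labelled SRMS shRNA than genes without it (median difference -0.19, interval -0.222 to -0.161, before the length trend is removed; medians of -0.07 and 0.02 with length, span, GC content and level removed), which goes against a swap only if the hairpin explanation holds, and that stays open. SRMS protein was not measured here.

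Of the 10 splits of the 6 libraries into 3 and 3, the real grouping gave 7969 genes by limma, and the highest of the other 9 gave 0 at the adjusted threshold, with 63 to 312 genes at an unadjusted p under 0.05 against 8650 for the real grouping; other tools were not run on the splits. Every other split puts libraries of both constructs on each side, so the difference between constructs widens its residual spread. Few calls in those splits were therefore to be had whatever the cause, and they do not estimate what chance gives. The number of splits as large, the real one included, was 1, and with 10 splits no share under 0.05 can be had. The 3 other splits that part every same-numbered pair gave 67 to 87 genes at an unadjusted p under 0.05, and the remaining 6 part only 1 pair.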
